A study of Mus musculus with 21 samples.

How the data were processed

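Strand-specific RNA sequencing of polyadenylated RNA had been done on 21 libraries of MEDEP cells in 7 groups of 3, described in the design text as biological replicates. The groups were 0, 12, 24, 36, 48 and 72 h of differentiation and 12 h with succinyl acetone (SA). The authors deposited 2 tables, with 1 column per library and 22483 genes each. The first holds estimated counts per gene, deposited by the authors without scaling for depth. Of its values 78.5% were whole numbers (tolerance 1e-06), and the column totals lay between 16.7 and 39.3 M counts. The second holds TPM (transcripts-per-million) per gene, computed and deposited by the authors. Per the submitters' processing notes kallisto, STAR 2.5.3a and DESeq2 were used, with the builds GRCm38.p5 and mm10, but the notes do not say which tool made which table. Of the 12360 tested gene IDs 12351 were found in GENCODE M21, 12311 of them protein coding, and positions were taken from there. The 23 symbols that occur more than once were kept apart by gene ID.

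Libraries of 1 group were compared before they were averaged: the chi-square per gene lay between 7.04 and 317 and the Spearman correlation between 0.948 and 0.978, so every pair differed by more than sampling noise. Estimated counts were rounded to whole numbers. Genes were kept when filterByExpr (minimum count 10) passed them over the 7 groups, and library sizes were scaled by TMM. Each comparison was a contrast of group means in 1 edgeR quasi-likelihood model (glmQLFit, glmQLFTest) of all 21 libraries, with Benjamini-Hochberg adjustment over the 12360 genes and a threshold of 0.05. All tests were 2-sided. The biological coefficient of variation was 11.6%. Fold changes with their standard errors are on the log2 scale, and normalized counts-per-million (CPM) are given as mean ± SD. The standard errors were derived from the quasi-likelihood test, as the size of the log2 change divided by the square root of F. They are approximate, above all for large changes and low counts. A gene with 0 counts in a group was set to a floor of 3 counts over the group, which gives a lower bound, and a gene with 1 to 3 counts has a ratio with an exact 95% counting interval. Intervals and floors cover counting error only.

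The 8 comparisons were the 5 steps of the time course, 72 h against 0 h, 24 h against 0 h, and 12 h with SA against 12 h. Genes that varied over the course were found by testing the 5 later times against 0 h together. Transient genes had a mean at an inner time at least 2-fold above, or below, both 0 h and 72 h, with an adjusted p of at most 0.05 in both contrasts. The paralogs of alpha globin (Hba-a1 and Hba-a2) and of adult beta globin (Hbb-bs and Hbb-bt) were also summed and tested. The 27 pathway lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 in 3 comparisons (12 h against 0 h, 72 h against 0 h and SA), and 8 lists of cell type markers were counted and summed. Comparisons, tests, lists, the rule for named genes and most alternatives were chosen before the data were examined. Named genes were those with the largest rises and falls among called genes with a mean count of at least 100 and no overlap of replicates, up to 2 called members in each direction of a list described, and a fixed panel of erythroid, stress and growth genes. Outside this rule are Gclm, Sqle and Foxo3 with SA, named after their values were seen. Some genes that the rule gives are not reported here. A list of 38 hypoxia-responsive genes (30 tested) and a list of 20 interferon genes were also put together after values were seen.

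Alternatives were the size factors of DESeq2 in edgeR, no count filter, library sizes without globin genes, the replicate number as a block, the compared libraries alone, DESeq2 (Wald test), limma-trend on log2(TPM + 1) for genes with a mean TPM of at least 1, the same with a pseudocount of 0.1 or with all genes above 0 in 3 libraries, a fold of at least 2, and each library left out in turn. For the lists an estimated correlation and fry were added. Replicate numbers were checked for pairing as the correlation of deviations from group means over 6265 genes, with every pair above 0.1 required. They paired the libraries at 24 h and 12 h (0.338 to 0.527), 48 h and 36 h (0.157 to 0.513), 72 h and 48 h (0.381 to 0.411), and 12 h with and without SA (0.387 to 0.465). The labels do not say what a number marks.

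The pipeline was tested on simulated data with the depths of these libraries. Changes were planted only in genes above a minimum expected count. At folds of 1.5, 2 and 4 the SA comparison recovered 64.2, 89.6 and 98.5% of them, with 4 false calls among 12204 genes (2.33% of its calls). The comparison of 72 h with 0 h recovered 67.2, 91.0 and 100%, with 15 false calls among 11923 genes, whereas limma on per-million values made 10253 false calls there, with a median of -1.08 for unchanged genes. In that simulation only the planted genes and the globins differed between 72 h and 0 h, so most genes were unchanged by design. In the real libraries most genes were called, so the simulation does not show which scale is right for them. Of 100 planted peaks 99 were found by the time course test and 98 as transient, with 7 and 0 other calls among 12257 genes. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.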

Results

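Polyadenylated RNA was measured by strand-specific sequencing in MEDEP cells, an erythroid progenitor line derived from mouse embryonic stem cells, here of the BRC5 line. The cells proliferated with stem cell factor (SCF), the ligand of the receptor Kit, and with the glucocorticoid dexamethasone. Differentiation started when both were withdrawn and 4 U/ml erythropoietin (Epo), the hormone that drives red cell production, was added. Libraries were made before the switch (0 h) and 12, 24, 36, 48 and 72 h after it, and at 12 h also from cells given Epo together with succinyl acetone (SA), an inhibitor of heme synthesis. Each of the 7 groups held 3 biological replicates, which gave 21 libraries. The total estimated count was 29.2 ± 4.66 M counts at 0 h (mean ± SD, n = 3 in this and every group), 30.1 ± 6.29 M at 12 h and 34.5 ± 4.33 M at 12 h with SA. It was 31.5 ± 7.23 M at 24 h, 24.0 ± 8.35 M at 36 h, 29.6 ± 6.87 M at 48 h and 33.1 ± 4.63 M at 72 h. The lowest library held 16.7 M (36 h, replicate 3) and the highest 39.3 M (12 h with SA, replicate 2). Of 22483 genes, 12360 had enough counts to be tested.

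Globin transcripts, which code for the protein chains of hemoglobin, took 0.0613 ± 0.0143% of counts at 0 h, 1.28 ± 0.107% at 12 h and 4.76 ± 0.441% at 24 h (mean ± SD, n = 3). Their share was 22.6 ± 0.224% at 36 h, 27.5 ± 1.39% at 48 h and 35.2 ± 3.07% at 72 h. At 12 h with SA it was 0.939 ± 0.0953%. Transcripts of the mitochondrial genome went the other way, from 6.30 ± 0.364% at 0 h to 1.56 ± 0.337% at 72 h. The 10 genes with the most counts took 7.0% of counts at 0 h and 44.9% at 72 h. A scale of shares of the library and the TMM scale used here differ, and how much of this comes from these genes was not tested. On the scale of transcripts-per-million values (TPM) the median log2 change of all tested genes was -0.09 at 12 h against 0 h, -0.32 at 24 h against 12 h and -1.84 at 36 h against 24 h. It was -0.47 at 48 h against 36 h, -0.45 at 72 h against 48 h and -3.27 at 72 h against 0 h. On the TMM scale these medians lay between -0.13 and 0.00, so every rise or fall given here is relative to the middle of the tested genes, not an amount per cell.

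**Figure D1:**
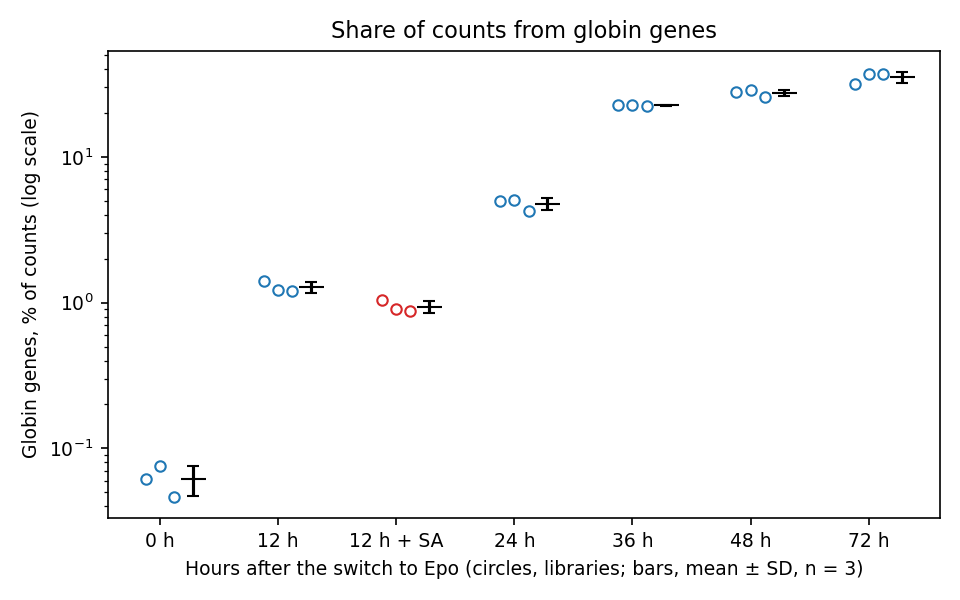
Share of counts from globin genes in percent on a log axis, with each of the 21 libraries as a circle and the mean ± SD (n = 3) as a bar beside each group. The share went from 0.0613% at 0 h to 35.2% at 72 h, and the 3 SA libraries (0.870 to 1.05%) lay below the 3 libraries at 12 h without SA (1.20 to 1.40%).

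The comparison of 12 h with 0 h asked what changed in the first hours after SCF and dexamethasone were replaced by Epo. All 8 tested enzymes on the heme synthesis list rose, among them Alas2, the erythroid form of the first enzyme of the pathway, by a log2 change of 4.60 ± 0.17 (SE, n = 3 against 3, adjusted p = 1.35e-14). This gene (ENSMUSG00000025270.13, GRCm38 chromosome X, 150547375 to 150570638, plus strand, protein coding) went from 14.2 ± 1.84 to 343.9 ± 8.06 normalized counts-per-million (CPM). Alas1, the other form of the first enzyme, is not on that list and was called lower, at -0.70. Of 24 genes of the red cell membrane and its skeleton 21 rose and none fell. The anion exchanger Slc4a1 (ENSMUSG00000006574.15, chromosome 11, 102348824 to 102366203, minus strand) rose by 7.33 ± 0.19, from 13.5 ± 1.46 to 2174 ± 246 CPM. Of 16 targets of Epo and its mediator STAT5 13 rose and 2 fell, led by Cish (ENSMUSG00000032578.7, chromosome 9, 107296026 to 107302784, plus strand), a feedback inhibitor of cytokine receptors, at 7.77 ± 0.20 and 190 ± 22.7 CPM against 0.869 ± 0.0577 CPM. Kit (ENSMUSG00000005672.12, chromosome 5, 75574916 to 75656722, plus strand) fell by 3.39 ± 0.22, from 985.9 ± 34.8 to 94.2 ± 8.94 CPM, and Myb, a regulator of progenitor growth, changed by -3.84 ± 0.21.

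Other erythroid genes changed as well. Summed over their paralogs, the alpha globins rose by 4.33 ± 0.19 and the adult beta globins by 4.58 ± 0.25 (log2 ± SE, n = 3 against 3). Of the 21 erythroid transcription regulators 15 rose, 1 fell and 5 did not pass, with Sox6 at 3.16 ± 0.14, Tal1 at 2.70 ± 0.09, Klf1 at 1.47 ± 0.11 and Gata1 at 1.23 ± 0.08. Of 12 genes that carry heme or iron across mitochondrial and other membranes 7 rose and 3 fell: the iron importer Slc25a37 rose by 4.68 ± 0.24 and Abcb10 by 2.83 ± 0.07, while the heme exporter Flvcr1 changed by -1.52 ± 0.10 and Slc25a28 by -0.88 ± 0.11. Tfrc, the transferrin receptor, rose by 2.43 ± 0.14 and Dmtn, of the membrane skeleton, by 3.80 ± 0.11. In the heme synthesis list Uros rose by 2.95 ± 0.08 and Fech, which inserts the iron, by 1.78 ± 0.12. Of 20 genes of terminal maturation 15 rose and 2 fell (adjusted p = 3.44e-09, and adjusted p = 0.148 with an estimated correlation). Of 10 globin and globin chaperone genes 9 rose and none fell, with a median log2 change of 3.75, or 3.49 with the gene at 0 counts set to its bound (adjusted p = 1.41e-05, and adjusted p = 0.0569 with an estimated correlation).

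Targets of the withdrawn factors fell more often than they rose. Of 15 targets of Kit and ERK signaling 11 fell and 2 rose, with a median log2 change of -3.01. The largest falls were those of the ETS factors Etv4 (ENSMUSG00000017724.14, chromosome 11, 101769742 to 101785371, minus strand) at -8.055 ± 0.64 and Etv5 at -7.66 ± 0.29. The phosphatase Dusp6 changed by -5.41 ± 0.37. The adjusted p of the list was 1.12e-06, and adjusted p = 0.0684 with an estimated correlation. Of 17 targets of the glucocorticoid receptor 10 fell and 2 rose: the kinase Sgk1 changed by -3.41 ± 0.13, Zfp36l2 by -3.29 ± 0.15 and Tsc22d3 by -0.94 ± 0.11, while the phosphatase Dusp1 rose by 4.58 ± 0.20. Of 13 regulators of stem and progenitor cells 9 fell and 4 rose (adjusted p = 0.188), with Gata2 at -2.87 ± 0.17 and, rising, the cytokine receptor subunits Csf2rb2 at 6.66 ± 0.34 and Csf2rb at 5.22 ± 0.32. Myc changed by -1.90 ± 0.20, and all 26 genes of ribosome biogenesis fell, with Polr1b at -1.72 ± 0.17 and Rrs1 at -1.64 ± 0.15 (list adjusted p = 2.12e-11, and adjusted p = 0.112 with an estimated correlation). Of 40 cytosolic ribosomal proteins 39 did not pass and 1 fell (adjusted p = 0.951).

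Cholesterol synthesis and 3 further lists had more rises than falls. Of 24 genes of cholesterol synthesis 21 rose and 1 fell, with Fdft1 at 2.18 ± 0.16 and Fdps at 2.01 ± 0.12 (adjusted p = 1.26e-06, and adjusted p = 0.318 with an estimated correlation). Among 24 genes of the G2 and M phases of the cell cycle 20 rose and 1 fell, with Aurka at 1.45 ± 0.14 (adjusted p = 0.0063, and adjusted p = 0.637 with an estimated correlation). Of 21 genes of autophagy and mitochondrial clearance 11 rose and 4 fell (adjusted p = 0.045, and adjusted p = 0.555 with an estimated correlation). Of 28 nuclear genes of the respiratory chain 16 rose and none fell (adjusted p = 0.0483, and adjusted p = 0.61 with an estimated correlation). Among the single genes with the largest changes, Apol11b rose by 7.86 ± 0.42, Ano3 by 7.45 ± 0.35, the histidine-degrading enzyme Hal by 7.36 ± 0.46 and Apol8 by 7.19 ± 0.25. The complement gene C7 had 1579 counts at 12 h against 3 at 0 h, a ratio of 532 (95% counting interval 182 to 2581), and Pdzk1ip1 a ratio of 264 (90.1 to 1284). Falls in this group were those of the transporter Abcb5 at -7.59 ± 0.37, Rasd1 at -7.09 ± 0.22, Fa2h at -6.51 ± 0.32, Klhl6 at -6.49 ± 0.25 and Neurog2 at -5.60 ± 0.32. Tespa1 was lower by a ratio of 350 (96.5 to 2895; 2 against 707 counts).

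In all, 6539 genes were called at 12 h against 0 h (3123 up, 3416 down), 2193 of them with a fold of at least 2 (1231 up, 962 down), by edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment. The replicates of both times did not overlap for 67.7% of genes, where chance gives 10%. Over the 27 lists, camera with a preset correlation of 0.01 called 14 (11 up, 3 down), and 6 held with an estimated correlation: heme synthesis (adjusted p = 0.00415), heme and iron transport (0.0393), membrane and skeleton (0.0186), erythroid regulators (0.00415), glucocorticoid targets (0.0393) and Epo and STAT5 targets (0.00166). With the preset correlation, other splits of the same libraries, with 0 genes called, still gave 10 to 16 lists. Each of these splits holds unequal numbers of both times on its sides, so part of the real change stays in it. The splits therefore cannot show whether the p-values for lists are too small. Those p-values depend on the correlation that is set and cannot be taken at face value. Adjusted over the list alone, the counts of members were as given, except cholesterol synthesis with 22 up and 1 down. Among the lists not called, iron-sulfur cluster assembly had 6 up and 6 down of 20 (8 and 6 adjusted over the list alone; adjusted p = 0.489), DNA replication 8 up and 3 down of 26 (7 and 2 adjusted over the list alone; adjusted p = 0.346) and glycolysis 7 up and 3 down of 19 (9 and 3 adjusted over the list alone; adjusted p = 0.234).

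The next step, 24 h against 12 h, followed the same culture without a change of medium factors. Of 24 cholesterol synthesis genes 22 rose and none fell, the same numbers adjusted over the list alone, with Hmgcs1 at 2.25 ± 0.16 and Idi1 at 1.97 ± 0.16 (log2 ± SE, n = 3 against 3). In the list of 24 G2 and M phase genes 17 rose and none fell (20 adjusted over the list alone), with a median of 0.47 (0.16 in TPM), among them the proliferation marker Mki67, which rose by 1.25 ± 0.20 from 1463 ± 89.3 to 3490 ± 220 CPM, and Ccna2 at 0.90 ± 0.17, which was not called in TPM. Of 26 DNA replication genes 14 rose (19 adjusted over the list alone), with a median of 0.37 (0.04 in TPM), and with Tyms at 0.90 ± 0.11, which was not called in TPM with a pseudocount of 0.1. Of 26 ribosome biogenesis genes 24 fell (25 adjusted over the list alone), with Npm1 at -1.21 ± 0.15 and Rrp9 at -1.10 ± 0.15. Of 20 terminal maturation genes 16 rose (18 adjusted over the list alone), with a median of 0.86 (0.51 in TPM), and with Ypel4 at 1.85 ± 0.22. Alas2 rose by 1.75 ± 0.15, Slc4a1 by 1.67 ± 0.15, the survival gene Bcl2l1 by 1.71 ± 0.14 and Tfrc by 1.21 ± 0.13, whereas Kit changed by -1.60 ± 0.21 and Myb by -1.57 ± 0.21. Of 5 tested markers of megakaryocytes and platelets 4 rose and none fell, with a median of 2.11 (1.13 in TPM). The largest rises were those of the platelet receptor gene Gp1ba (4.47 ± 0.28), Mrvi1 (3.79 ± 0.31) and Clec4g (3.40 ± 0.28). The largest falls were those of the cysteine-producing enzyme Cth (-3.03 ± 0.36), Ltbp1 (-3.00 ± 0.32) and Ehf (-2.94 ± 0.36). The test called 5079 genes, 2358 up and 2721 down, 1165 of them with a fold of at least 2, and 58.6% of genes had no overlap of replicates, where chance gives 10%. On the TPM scale, tested with limma, 602 genes were up and 4286 down.

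Between 24 and 36 h came the step with the most genes called. Of 21 interferon-stimulated genes, which act in antiviral defense, 20 rose and 1 fell, the same numbers adjusted over the list alone, with a median log2 change of 4.88 (0.53 in TPM). Oasl2 rose by 8.33 ± 0.31 (SE, n = 3 against 3), to 413.7 ± 122 CPM. All 5 tested markers of megakaryocytes and platelets also rose, with a median of 3.95 (1.498 in TPM), as did 2 of 3 for macrophages, 1 of 2 for neutrophils and 1 of 2 for lymphocytes (median -0.23 in TPM), and none fell. The cell cycle inhibitor Cdkn1b rose by 3.55 ± 0.13, from 47.3 ± 5.43 to 553.7 ± 105 CPM, while all 26 DNA replication genes fell, with Ung at -2.41 ± 0.21 and Pold1 at -2.21 ± 0.16. All 26 ribosome biogenesis genes fell as well, with Utp20 at -2.25 ± 0.12 and Nolc1 at -2.01 ± 0.17. Both lists kept these counts adjusted over the list alone. All 10 globin and globin chaperone genes rose, with a median of 2.59 (1.73 in TPM), and the sums of alpha and of adult beta globins by 3.13 ± 0.18 and 3.33 ± 0.23. Alas2 rose by 3.01 ± 0.16 and Bcl2l1 by 3.34 ± 0.14, and Kit changed by -1.85 ± 0.23.

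In lists of stress and maturation genes, members that rose in the same step outnumbered those that fell, on the TMM scale. Of 32 genes of the HRI and ATF4 response, which cells use under heme or amino acid shortage, 25 rose and 4 fell relative to the middle of all genes, with a median of 1.23 that was -0.81 in TPM. Atf5 rose by 4.53 ± 0.22, Slc7a11, a cystine transporter, by 4.25 ± 0.41, Trib3 by 4.00 ± 0.39, Ddit3 by 3.33 ± 0.27 and the heme-regulated kinase Eif2ak1 by 2.72 ± 0.10. Of 20 BACH1 and heme-responsive genes 16 rose and 1 fell, with a median of 1.72 that was -0.37 in TPM, and the heme-degrading enzyme Hmox1 rose by 3.23 ± 0.31. Of 21 autophagy genes 15 rose and 3 fell, with a median of 1.28 that was -0.77 in TPM, and Bnip3l, which marks mitochondria for removal, rose by 2.13 ± 0.13 (not called in TPM). Of 20 terminal maturation genes 17 rose and 1 fell, with a median of 2.16 (0.09 in TPM), and with Xpo7 at 6.26 ± 0.13 and Ube2o at 5.70 ± 0.20. Of 24 membrane and skeleton genes 20 rose and 2 fell, with a median of 0.96 that was -1.05 in TPM, and with Tmcc2 at 6.11 ± 0.21 and Epb41 at 3.56 ± 0.17. These member counts were the same adjusted over the list alone. Other genes with the largest changes were Mmp13, a collagenase with 668 counts at 36 h and 0 at 24 h (at least 589-fold higher, with a floor of 3 counts over the group), Casp12 (9.40 ± 0.53), Gvin1 (9.03 ± 0.36), the phosphatase Ptpn6 (-3.69 ± 0.18), Vwa5b2 (-3.66 ± 0.26) and Nme4 (-3.49 ± 0.15). The test called 9044 genes (4219 up, 4825 down), 5089 of them with a fold of at least 2 (2758 up, 2331 down), and 76.2% of genes had no overlap of replicates, where chance gives 10%. On the TPM scale 410 were up and 8486 down, and 36 h replicate 1 stood apart in stromal transcripts (33.3 CPM summed over 11 markers, against 0.144 and 0.418 CPM in replicates 2 and 3).

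From 36 to 48 h most G2 and M phase and DNA replication genes fell. The G2 and M phase list had 23 of 24 genes down and none up, with Aurkb at -1.54 ± 0.14, Bub1 at -1.52 ± 0.20 and Mki67 at -0.92 ± 0.19 (log2 ± SE, n = 3 against 3). Of 26 DNA replication genes 25 fell, with Gins1 and Gins2 both at -1.46. Of 24 cholesterol synthesis genes 22 fell and 1 rose, with Ebp at -1.65 ± 0.12 and Tm7sf2 at -1.65 ± 0.18. Of 21 interferon-stimulated genes 20 rose and none fell, with a median of 2.34 (1.39 in TPM). Ifit3 rose by 3.74 ± 0.58, Rsad2 by 3.11 ± 0.27 and Ifit1 by 3.09 ± 0.25, from 61.5 ± 11.2 to 526 ± 102 CPM. These 4 lists kept their counts adjusted over the list alone. Of 40 cytosolic ribosomal proteins 32 fell (34 adjusted over the list alone), and 25 of 28 nuclear respiratory chain genes fell (25 adjusted over the list alone). Hmox1 rose by 1.58 ± 0.29 and Alas2 by 0.73 ± 0.15, the latter not called in TPM. Klf1 changed by -0.74 ± 0.10 and Tfrc by -0.61 ± 0.13. Besides Rsad2 and Ifit1, Tbata (4.30 ± 0.65) was among the largest rises, and Egln1 (-2.13 ± 0.40), Higd1a (-1.83 ± 0.39) and the desaturase Scd2 (-1.75 ± 0.21) were the largest falls. Egln1 and Higd1a respond to hypoxia, and the median of a list of such genes deviated from the other replicates by -0.81 in 36 h replicate 1 and by 0.84 in 36 h replicate 2. The test called 6153 genes (2476 up, 3677 down), 1637 of them with a fold of at least 2, and 51.4% of genes had no overlap of replicates, where chance gives 10%. The split between rises and falls depended on the scaling: it was 3197 up and 2961 down with the size factors of DESeq2 in edgeR, 3190 and 3024 in DESeq2 itself and 246 and 5954 on the TPM scale.

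From 48 to 72 h all 21 interferon-stimulated genes rose, with a median of 2.74 (1.62 in TPM), and with Ifit3 at 4.22 ± 0.32 and Ifit2 at 4.04 ± 0.27 (log2 ± SE, n = 3 against 3). Their summed level went from 4168 ± 511 CPM at 48 h to 20029.9 ± 5242 CPM at 72 h (mean ± SD, n = 3), and the chemokine Cxcl10 rose by 5.20 ± 0.18, from 7.23 ± 2.20 to 261 ± 66.2 CPM. Among G2 and M phase genes 23 of 24 fell and 1 rose, with Aurkb at -2.49 ± 0.18 and Cenpf at -2.39 ± 0.20. Of 24 membrane and skeleton genes 18 fell and 2 rose (18 and 3 adjusted over the list alone), with Rhag at -2.34 ± 0.13 and Aqp1 at -1.98 ± 0.18. All 13 transcripts of the mitochondrial genome fell, with mt-Nd3 at -2.23 ± 0.13 and mt-Nd4l at -1.79 ± 0.14, and so did 36 of 40 cytosolic ribosomal proteins, with Rpl3 at -1.38 ± 0.11 and Rpl14 at -1.35 ± 0.14. Of the 8 enzymes on the heme synthesis list 6 fell and none rose. Of 26 ribosome biogenesis genes 19 rose and 1 fell (21 and 1 adjusted over the list alone), with Wdr43 at 1.46 ± 0.10 and Dkc1 at 1.45 ± 0.24 (not called in TPM without a minimum level), a median of 0.64 that was -0.05 in TPM. The other lists of this step had the same counts adjusted over the list alone. Tfrc changed by -1.51 ± 0.13, Mki67 by -1.23 ± 0.20, Klf1 by -1.11 ± 0.11 and Hmox1 by 1.36 ± 0.29, the last not called in TPM. Alas2 did not pass, at 0.02 ± 0.15 (adjusted p = 0.9), and was -0.70 in TPM. Cald1 (8.32 ± 0.86) and Trim30c (7.18 ± 0.55) rose most, and the pyruvate kinase Pklr (-3.35 ± 0.13), Sox6 (-3.20 ± 0.14) and Gas7 (-2.98 ± 0.29) fell most. The test called 7322 genes (3058 up, 4264 down), 3152 of them with a fold of at least 2, and 56.0% of genes had no overlap of replicates, where chance gives 10%. The split was 3750 up and 3627 down with the size factors of DESeq2 in edgeR, 3808 and 3645 in DESeq2 itself and 437 and 5651 on the TPM scale.

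**Figure D2:**
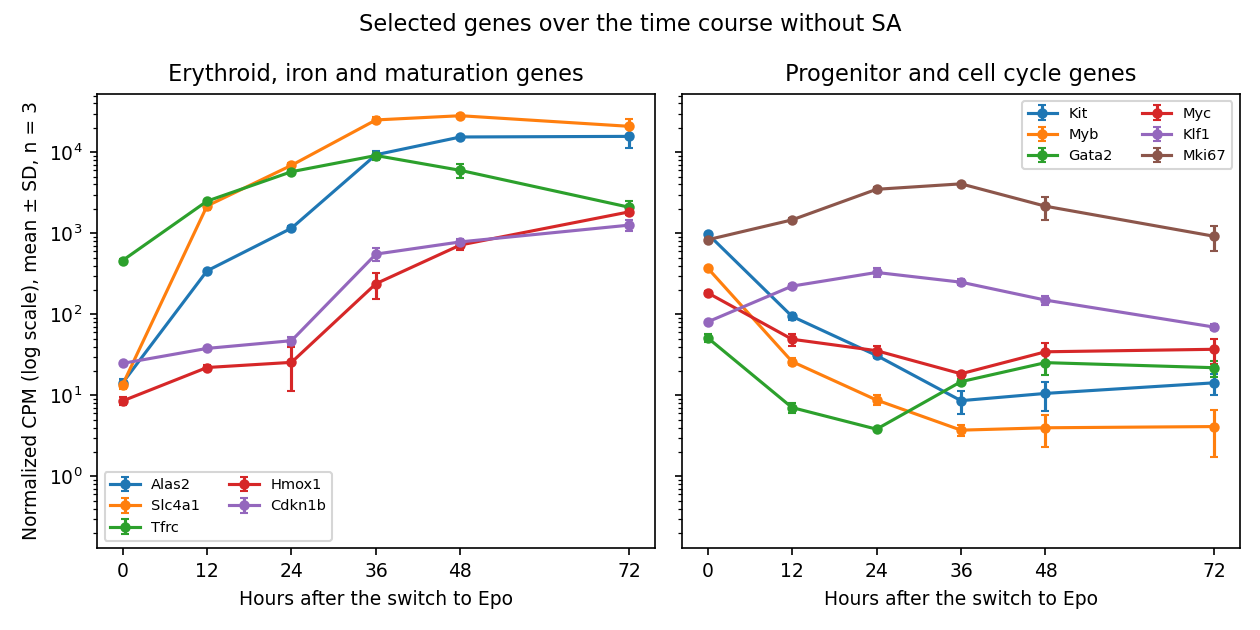
Normalized counts-per-million on a log axis against hours after the switch to Epo for 5 erythroid, iron and maturation genes (left) and 6 progenitor and cell cycle genes (right), as mean ± SD (n = 3) on the TMM scale. Tfrc went from 461 CPM at 0 h to 9114 CPM at 36 h and 2093 CPM at 72 h, and Kit from 985.9 CPM at 0 h to 8.60 CPM at 36 h.

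The comparison of 72 h with 0 h covered the whole time course. Alas2 rose by 10.11 ± 0.22 (log2 ± SE, n = 3 against 3, adjusted p = 3.03e-19), Slc4a1 by 10.60 ± 0.22 and Fech by 4.27 ± 0.14 (not called in TPM without a minimum level). On the heme synthesis list 6 of 8 enzymes rose and none fell, with a median of 3.21 that was -0.42 in TPM, where the middle of all genes was -3.27. All 10 globin and globin chaperone genes rose, with a median of 10.52 (7.31 in TPM), the alpha globin sum by 10.52 ± 0.25 and the adult beta globin sum by 11.54 ± 0.33. All 21 interferon-stimulated genes rose, with a median of 9.60 (3.43 in TPM), also with the gene at 0 counts set to its bound. Ifit1 (ENSMUSG00000034459.8, chromosome 19, 34640871 to 34650009, plus strand) rose by 12.92 ± 0.40, and Mx2 had 2024 counts at 72 h and 0 at 0 h, at least 2129-fold higher with a floor of 3 counts over the group. Kit fell by 6.11 ± 0.25, from 985.9 ± 34.8 to 14.3 ± 4.27 CPM, and Myb changed by -6.49 ± 0.26. Klf1 did not pass, at -0.21 ± 0.11 (adjusted p = 0.0635); its value was 0.06 with the size factors of DESeq2 in edgeR, 0.02 in DESeq2 itself and -3.86 in TPM, where it was called. Mki67 did not pass either, at 0.14 ± 0.19 (adjusted p = 0.485), and was -3.79 in TPM, where it was called. Without 72 h replicate 1 the values were -0.30 for Klf1 and 0.37 for Mki67, both called, and without 72 h replicate 3 Mki67 was at -0.15. Klf1 was also called without 0 h replicate 2 (-0.27), with no count filter (-0.43), and without 24 h replicate 1 and 36 h replicate 1 together (-0.24, chosen after the values were seen). Markers of macrophages, neutrophils and lymphocytes were also higher at 72 h, with summed levels of 11.5 ± 0.901, 6.58 ± 1.19 and 4.71 ± 0.736 CPM against 0.835 ± 0.0313, 0.0311 ± 0.0385 and 0.141 ± 0.0582 CPM at 0 h (mean ± SD, n = 3).

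Among the lists that camera called higher at 72 h, relative to the middle of all genes, were those of maturation, stress and clearance, with the preset correlation but none with an estimated one. Of 20 terminal maturation genes 18 rose and 2 fell, with Ypel4 at 12.03 ± 0.33 and Isg20 at 7.67 ± 0.26, a median of 4.26 (0.44 in TPM). Of 24 membrane and skeleton genes 20 rose and 4 fell, a median of 1.76 that was -1.80 in TPM, with Tmcc2 at 10.70 ± 0.25, the water channel Aqp1 at -1.95 ± 0.18 and Rhag at -1.48 ± 0.12. Of 21 autophagy genes 17 rose and 4 fell, a median of 2.71 that was -0.68 in TPM, with the cargo receptor Sqstm1 at 7.11 ± 0.21 and Gabarap at 5.62 ± 0.15. Of 20 BACH1 and heme-responsive genes 14 rose and 6 fell, a median of 3.01 that was -0.81 in TPM, with Hmox1 (ENSMUSG00000005413.8, chromosome 8, 75093621 to 75100589, plus strand) at 7.76 ± 0.38, from 8.53 ± 0.94 to 1839 ± 141 CPM. Of 32 HRI and ATF4 genes 20 rose and 10 fell, a median of 1.79 that was -1.65 in TPM. The phosphatase subunit Ppp1r15a rose by 8.87 ± 0.19 and Trib3 by 7.48 ± 0.48, while the serine synthesis enzymes Psat1 and Phgdh changed by -5.66 ± 0.12 and -5.57 ± 0.19. Of 13 p53 targets 10 rose and 3 fell, a median of 3.46 that was -0.30 in TPM, with Trp53inp1 at 7.26 ± 0.17 and Bbc3 at 7.11 ± 0.28. Of 7 CDK inhibitors 6 rose and 1 fell, a median of 2.55 that was -2.11 in TPM, with Cdkn1b at 5.67 ± 0.15. Of 16 Epo and STAT5 targets 14 rose and 2 fell, a median of 2.23 that was -1.08 in TPM, with Pim1 at 10.43 ± 0.21 and Cish at 8.94 ± 0.21. Of 21 erythroid regulators 14 rose and 4 fell, a median of 2.01 that was -1.58 in TPM, with Nfe2 at 4.79 ± 0.09 and Foxo3 at 4.56 ± 0.14.

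The 6 lists that camera called lower at 72 h with the preset correlation, and none with an estimated one, concerned ribosomes, the cell cycle and respiration. Of 26 ribosome biogenesis genes 25 fell, with Utp20 at -5.54 ± 0.14 and Nop56 at -4.41 ± 0.16. Of 26 DNA replication genes 24 fell and 1 rose, with the polymerase Pole at -5.17 ± 0.18. For the G2 and M phases 22 of 24 genes fell and 1 rose, with Aurkb at -4.76 ± 0.17. The rising gene was Nusap1, at 468.6 against 166 CPM, whose log2 change was -2.39 in TPM. Of 40 cytosolic ribosomal proteins 36 fell and 3 rose, with Rpl3 at -2.84 ± 0.11 and, rising, Rpl28 at 1.76 ± 0.13, which was -1.71 in TPM. Of 28 nuclear respiratory chain genes 27 fell and 1 rose, with Ndufa10 at -2.79 ± 0.08 and Ndufs8 at -2.66 ± 0.13. Of 13 mitochondrial genome transcripts 11 fell and 1 rose, with mt-Nd3 at -4.92 ± 0.14 and, rising, mt-Co1 at 1.18 ± 0.09, which was -2.63 in TPM. Iron uptake and storage genes went both ways, 9 up and 8 down of 18 (adjusted p = 0.636), with the ferritin light chain Ftl1 at 6.75 ± 0.20. So did those of heme and iron transport, 7 up and 5 down of 12 (adjusted p = 0.236), iron-sulfur cluster assembly, 8 up and 10 down of 20 (adjusted p = 0.736), and chromatin condensation, 8 up and 8 down of 16 (adjusted p = 0.727). For the last pair of lists the median (-0.45 and -0.19) had the other sign than the direction of the test, and for chromatin condensation it was 0.08 with the size factors of DESeq2 in edgeR. Of 19 glycolysis genes 12 fell and 3 rose, with a median of -2.93 (adjusted p = 0.221), and of 13 stem and progenitor regulators 9 fell and 4 rose, with a median of -1.71 (adjusted p = 0.695). Also not called were the glucocorticoid targets with 9 up and 7 down of 17 (adjusted p = 0.359), the Kit and ERK targets with 5 up and 7 down of 15 (adjusted p = 0.597) and cholesterol synthesis with 11 up and 9 down of 24 (adjusted p = 0.472). Adjusted over the list alone, the 27 lists had the same counts at 72 h as over all genes, up and down.

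Single genes with the largest changes at 72 h against 0 h included Casp12 (ENSMUSG00000025887.10, chromosome 9, 5345430 to 5373032, plus strand), with 2958 counts against 0 and at least 3112-fold higher. Sstr5 (at least 1218-fold), Fbxo41 (at least 1168-fold) and Apol9b (at least 1073-fold) also had 0 counts at 0 h, each with a floor of 3 counts over the group. Fam180a, with 1 count at 0 h, had a ratio of 13894 (95% counting interval 2492 to 548915), and Oasl2 rose by 12.64 ± 0.37. Crtap, which takes part in collagen modification, was lower by a ratio of 289 (79.9 to 2389), Adam12 by 280 (77.5 to 2316), Etv4 by 195 (53.9 to 1613) and Atp23 by 137 (37.8 to 1133), each with 2 counts at 72 h. Abcb5 changed by -7.85 ± 0.46, the nucleoside transporter Slc28a2 by -7.69 ± 0.28, Pkd1l3 by -7.45 ± 0.27 and Cdca7l by -7.13 ± 0.20. The test called 11102 genes (5354 up, 5748 down), 9012 of them with a fold of at least 2, and 89.5% of genes had no overlap of replicates, where chance gives 10%. Camera with the preset correlation called 18 of 27 lists (12 up, 6 down), from terminal maturation (adjusted p = 3.34e-12) to CDK inhibitors (adjusted p = 0.0488). With an estimated correlation it called 0, and fry called 23. The smallest was adjusted p = 0.0896 with an estimated correlation, for p53 targets, followed by adjusted p = 0.135 for the interferon-stimulated genes. With the preset correlation, other splits of the same libraries, with 0 genes called, still gave 10 to 17 lists. Part of the real change stays in these splits too, so they cannot show whether the p-values for lists are too small. Since no list was called with an estimated correlation, the p-values with the preset cannot be taken at face value. The split of called genes was 5801 up and 5286 down with the size factors of DESeq2 in edgeR, 7021 and 5322 in DESeq2 itself, 6784 and 6114 with no count filter and 501 and 8661 on the TPM scale.

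**Figure D3:**
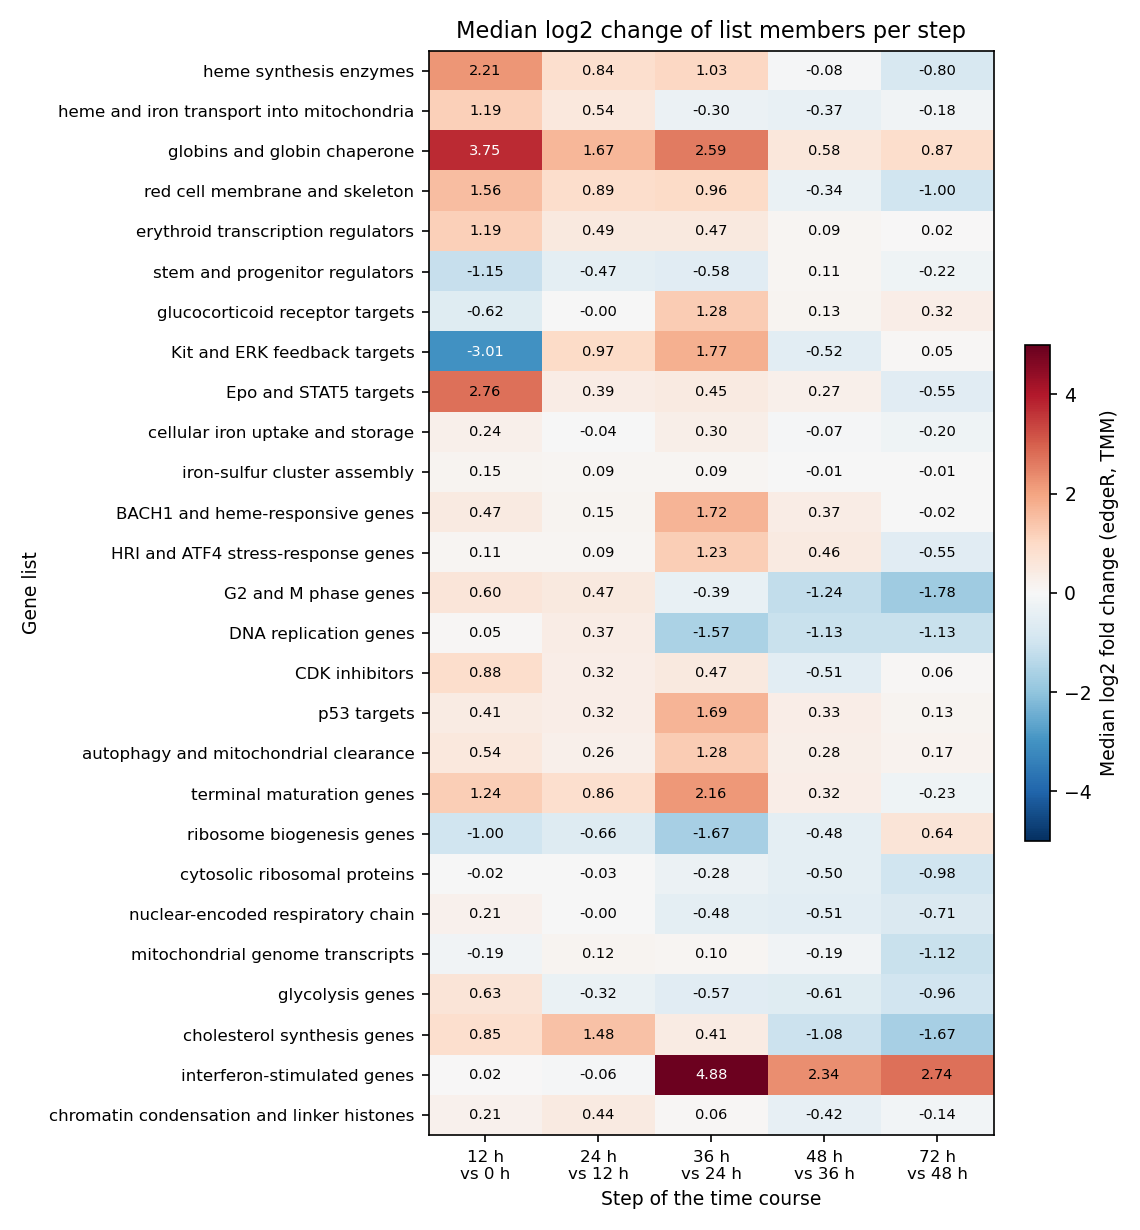
Median log2 change (edgeR, TMM scale) of the members of the 27 gene lists in the 5 steps of the time course, as color and number, relative to the middle of all tested genes. Interferon-stimulated genes had medians of 4.88, 2.34 and 2.74 in the last 3 steps (0.53, 1.39 and 1.62 in TPM), and cholesterol synthesis genes 1.48 (1.21 in TPM) at 24 h against 12 h and -1.67 at 72 h against 48 h; in TPM every positive median of up to 1.77 at 36 h against 24 h was negative.

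Across the whole course without SA, 12059 genes (97.6% of those tested) varied between times. A peak at 12, 24, 36 or 48 h of at least 2-fold over both 0 h and 72 h was found for 1134 genes and a dip for 828, 26 of which had both. Of the 24 cholesterol synthesis genes 22 peaked, among them Hmgcs1 and Sqle, as did 15 of 24 genes of the G2 and M phases, with Mki67 and Aurka, and 12 of 24 membrane and skeleton genes, with Rhag. Dips were found for 6 of 15 Kit and ERK targets, with Dusp6 and Etv5, for 4 of 13 stem and progenitor regulators, with Gata2 and Myc, and for 5 of 26 ribosome biogenesis genes. Most peaks were highest at 36 h (409 genes) or 24 h (344 genes), and most dips lowest at 36 h (289 genes) or 24 h (247 genes). The balance of peaks and dips depended on the scaling, with 937 peaks and 1032 dips under the size factors of DESeq2.

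The comparison at 12 h with and without SA asked what a block of heme synthesis changed in cells given Epo. Alas1 (ENSMUSG00000032786.16, chromosome 9, 106233455 to 106248654, minus strand), the form of the first enzyme of heme synthesis that most cells use, rose by a log2 change of 2.64 ± 0.13 (SE, n = 3 against 3, adjusted p = 1.61e-10), from 6.47 ± 0.483 to 40.3 ± 1.59 CPM. Its level at 0 h was 10.5 ± 0.736 CPM. Tfrc (ENSMUSG00000022797.15, chromosome 16, 32608920 to 32632794, plus strand), the transferrin receptor that brings iron into the cell, fell by 1.01 ± 0.13 (adjusted p = 0.000404; not called in TPM), from 2493 ± 22.6 to 1241 ± 78.4 CPM. The glucose transporter Slc2a1 (ENSMUSG00000028645.11, chromosome 4, 119108711 to 119137983, plus strand) fell by 2.78 ± 0.33 (adjusted p = 0.000228), from 19.8 ± 2.08 to 2.88 ± 0.798 CPM. The heme oxygenase Hmox1 fell by 1.58 ± 0.30 (adjusted p = 0.0194), from 22.1 ± 1.46 to 7.36 ± 1.13 CPM. Several erythroid genes did not pass this test: Alas2 changed by -0.28 ± 0.15 (adjusted p = 0.873), Fech by -0.18 ± 0.12 (adjusted p = 0.951), the alpha globin sum by -0.39 ± 0.17 (adjusted p = 0.737) and the adult beta globin sum by -0.54 ± 0.22 (adjusted p = 0.687). With the 6 compared libraries alone Alas2 (-0.30), Fech (-0.20), Hbb-bs (-0.63) and Hbb-bt (-0.51) were called, and with the replicate block the regulator Foxo3 (-0.55 ± 0.11) was, a gene picked after its value was seen.

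**Figure D4:**
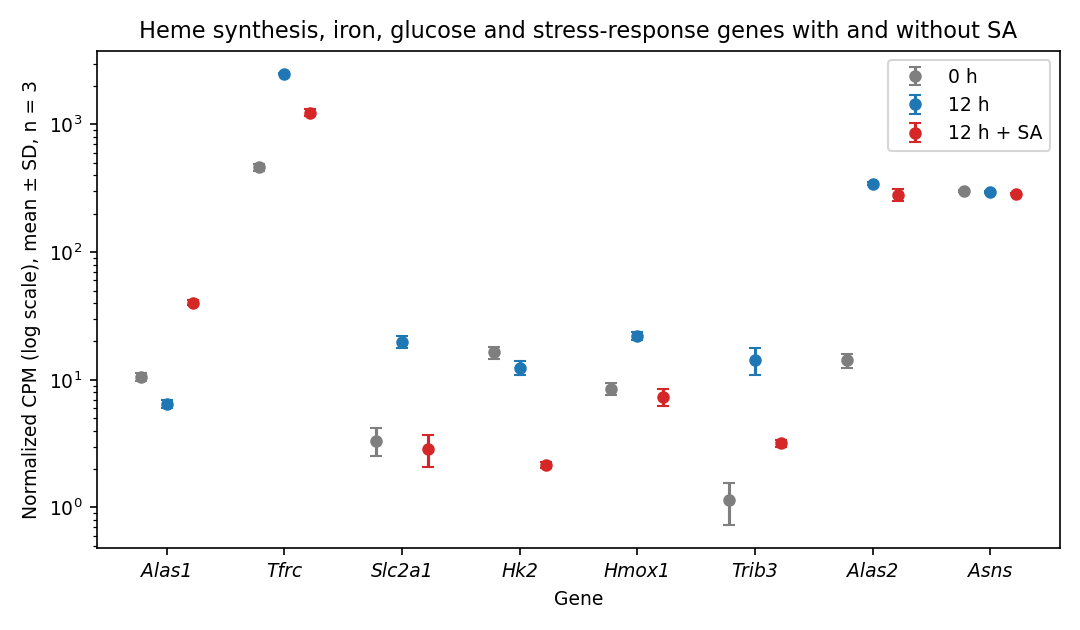
Normalized counts-per-million on a log axis (mean ± SD, n = 3) of 8 genes at 0 h, at 12 h and at 12 h with SA. Alas1 was 40.3 CPM with SA against 6.47 CPM without, and Slc2a1 2.88 against 19.8 CPM.

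Groups of genes with SA showed more falls than rises. Of 19 glycolysis genes 3 fell and none rose (7 fell adjusted over the list alone), with a median of -0.83 (adjusted p = 2.06e-16, and adjusted p = 0.0805 with an estimated correlation). Among them were Slc2a1, the lactate exporter Slc16a3 at -2.97 ± 0.53 and the hexokinase Hk2 at -2.54 ± 0.48. Of 32 HRI and ATF4 genes 2 fell and none rose (3 fell adjusted over the list alone), namely the pseudokinase Trib3 at -2.17 ± 0.39 and the folate enzyme Mthfd2 at -0.64 ± 0.11 (list adjusted p = 1.37e-09, and adjusted p = 0.142 with an estimated correlation). Atf4 itself (0.01 ± 0.11), Ddit3 (-0.33 ± 0.25) and Asns (-0.05 ± 0.11) did not pass, nor did the kinase Eif2ak1 (-0.03 ± 0.10). Ddit3 was called with the compared libraries alone (-0.34). Of 20 BACH1 and heme-responsive genes Alas1 rose and 3 fell, the same numbers adjusted over the list alone: Trib3, Hmox1 and Gclm, of glutathione synthesis, at -0.61 ± 0.12 (list adjusted p = 0.077). Of 18 iron uptake and storage genes Tfrc fell, also adjusted over the list alone, and the rest did not pass (adjusted p = 0.0708).

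Of 16 Epo and STAT5 targets 2 fell, also adjusted over the list alone (adjusted p = 4.68e-07, and adjusted p = 0.0717 with an estimated correlation). None of 10 globin and globin chaperone genes passed, over all genes or adjusted over the list alone, but their median was -0.55 (adjusted p = 2.28e-05, and adjusted p = 0.104 with an estimated correlation). Nor did any of the 8 enzymes on the heme synthesis list, which leaves out Alas1, with a median of -0.18 (adjusted p = 0.023, and adjusted p = 0.462 with an estimated correlation). Cholesterol synthesis genes had a median of -0.19 with no member called (1 fell adjusted over the list alone; adjusted p = 9.34e-08, and adjusted p = 0.355 with an estimated correlation), glucocorticoid targets -0.15 (none called, 1 fell adjusted over the list alone; adjusted p = 0.0106, and adjusted p = 0.142 with an estimated correlation) and membrane and skeleton genes -0.04 (none called, 2 fell adjusted over the list alone; adjusted p = 0.0248, and adjusted p = 0.617 with an estimated correlation). Ribosome biogenesis genes had a median of 0.17 with none called (adjusted p = 6.07e-06, and adjusted p = 0.355 with an estimated correlation). Other genes with the largest falls were Ankrd37 at -3.63 ± 0.72, Col4a3 at -1.75 ± 0.35 and Mgarp at -1.73 ± 0.28, and Sh2d4b rose by 1.46 ± 0.29. Several of these respond to low oxygen: of 30 tested genes of a hypoxia-responsive list put together after the values were seen, 5 fell with SA and none rose (22 fell adjusted over the list alone), with a median of -0.90. With the replicate number as a block Bnip3 (-2.40), Fam162a (-1.26), Pfkp (-1.865) and Egln1 (-1.11) of this list were called as well. Among cells without SA the same list deviated from its other replicates by -1.004 in 24 h replicate 1 and by -0.81 in 36 h replicate 1. In replicates 2 and 3 it deviated the other way, by 0.67 and 0.31 at 24 h and by 0.84 and 0.05 at 36 h. Within the compared groups it deviated by -0.19 to 0.16 at 12 h without SA and by at most 0.05 with SA.

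**Figure D5:**
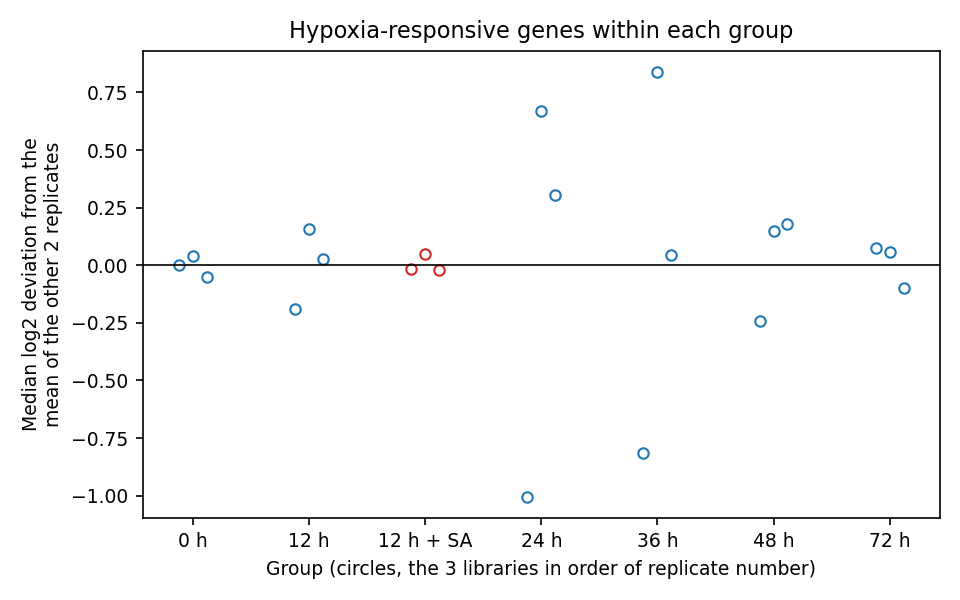
Median log2 deviation of 30 hypoxia-responsive genes in each of the 21 libraries from the mean of the other 2 replicates of its group. The value was -1.004 in 24 h replicate 1, -0.81 in 36 h replicate 1 and 0.84 in 36 h replicate 2.

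The SA comparison called 47 genes, 2 up (Alas1 and Sh2d4b) and 45 down, 27 of them with a fold of at least 2. Of the 12360 tested genes 759 had an unadjusted p under 0.05, where chance alone gives a share of 0.05. No overlap of replicates was found for 24.2% of genes, where chance gives 10%. Leaving out 1 library at a time gave 31, 13 and 18 genes without 12 h replicates 1, 2 and 3 and 17, 11 and 13 without SA replicates 1, 2 and 3. Alas1, Slc2a1 and Tfrc were called without any 1 of the 6 libraries. Sh2d4b, Ankrd37 and Gclm were lost whichever of the 6 was left out. Col4a3 was lost without 12 h replicates 1 or 2 or SA replicates 2 or 3, and Hk2, Trib3, Hmox1 and Mthfd2 without any library other than 12 h replicate 1. Slc16a3 was lost without 12 h replicate 2 or any SA replicate, and Mgarp without 12 h replicate 2 or SA replicates 1 or 2. With the replicate number as a block the count was 84, with DESeq2 151 (31 up, 120 down), with the 6 compared libraries alone 465 (89 up, 376 down), and with 24 h replicate 1 and 36 h replicate 1 left out of the model, a choice made after the values were seen, 81. In TPM, Mthfd2, Gclm and Tfrc were not called, nor was Col4a3 without a minimum level. Camera called 9 of 27 lists (1 up, 8 down), 0 with an estimated correlation, and fry called 1, the Epo and STAT5 targets. With the preset correlation, other splits of these 6 libraries gave 3 to 9 lists. Part of the real change stays in these splits, so they cannot show whether the p-values for lists are too small. Since no list was called with an estimated correlation, the p-values with the preset cannot be taken at face value. With hypoxia-responsive genes taken out of every list, a choice made after the values were seen, camera called 7, without glycolysis (adjusted p = 0.149) and glucocorticoid targets (adjusted p = 0.0641).

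Set beside differentiation itself, the comparison of 24 h with 0 h shares no library with that of SA. It called 8151 genes (3967 up, 4184 down; 1794 and 5017 on the TPM scale), 3883 of them with a fold of at least 2 (1968 up, 1915 down), and 75.1% of genes had no overlap of replicates, where chance gives 10%. Alas2 rose by 6.35 ± 0.19, Tfrc by 3.64 ± 0.14 and Mki67 by 2.07 ± 0.20 (log2 ± SE, n = 3 against 3). Apol11b rose by 10.37 ± 0.43, Clec4g was at least 628-fold higher with a floor of 3 counts over the group, and Apol10a had a ratio of 3567 (95% counting interval 639.7 to 140934). Etv4 was lower by a ratio of 359 (123 to 1743), Tespa1 by 309 (85.2 to 2556), and Abcb5 changed by -7.99 ± 0.39. Of the 47 genes called with SA 33 had the opposite direction at 24 h, 9 the same and 5 were not called there. Among the 45 that fell with SA, 32 rose at 24 h, where independence would give 14.4, and 8 fell, where it would give 15.2. Across all 12360 genes, which are not independent replicates, the log2 changes of both comparisons correlated with r = -0.16 (Pearson) and -0.26 (Spearman). The number with opposite direction was 56 with the replicate block, and 62, 3 and 3 without replicates 1, 2 and 3. In the same settings the number with the same direction was 20, and 17, 0 and 0.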

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

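Of the alternatives, 24 h replicate 1 and 36 h replicate 1 left out together and the 2 that leave hypoxia-responsive genes out were chosen after seeing the data. Counts within 1.5 times the reported value were obtained for 72 h against 0 h, the time course genes and the transient genes under every alternative run. With a fold of at least 2 the counts were 2193 (12 h against 0 h), 1165 (24 h against 12 h), 5089 (36 h against 24 h), 1637 (48 h against 36 h), 3152 (72 h against 48 h), 3883 (24 h against 0 h) and 27 (SA), because fewer genes meet 2 criteria. For 12 h against 0 h, limma on log2(TPM + 0.1) called 3724 genes against 6539, and the cause was not tested. Every other alternative kept the first 6 of these counts within 1.5 times the reported ones.

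Among the counts of called genes, the 47 with SA moved most. It was 74 with no count filter, 81 without 24 h replicate 1 and 36 h replicate 1, 465 with the 6 compared libraries alone, 16 and 114 with limma on log2(TPM + 0.1) and on all genes above 0 in 3 libraries, and 151 with DESeq2. The reported model takes the spread of a gene from all 21 libraries, later times included, and the 6 compared libraries alone give their own spread. How much of the 465 this accounts for, and the cause of the other changes, was not tested. The count was 55 with the size factors of DESeq2 in edgeR, 47 with library sizes without globins, 36 with limma on log2(TPM + 1) and 42 with hypoxia-responsive genes left out. Without 1 library the counts lay between 11 and 31 (SA), where 2 libraries remain in 1 arm, 5869 and 5960 (12 h against 0 h), 4072 and 4503 (24 h against 12 h), 8561 and 8960 (36 h against 24 h), 5336 and 6103 (48 h against 36 h), 6832 and 7215 (72 h against 48 h), 11033 and 11176 (72 h against 0 h), and 7607 and 7792 (24 h against 0 h). The number of SA genes with the opposite direction at 24 h against 0 h, 33, was 62 without replicate 1 and 3 without replicate 2 or 3. The number with the same direction, 9, was 17 without replicate 1 and 0 without replicate 2 or 3.

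With an estimated correlation camera called 6 lists at 12 h (14 with the preset), 0 at 72 h (18) and 0 with SA (9); the cause was not tested. Fry, which tests no list against other genes, called 24, 23 and 1. Without 1 library the counts of lists were 13 to 15, 17 to 18 and 7 to 12. With hypoxia-responsive genes taken out 7 lists were called with SA. Apart from those settings, the respiratory chain list at 12 h lost its call with the size factors of DESeq2 (adjusted p = 0.0626), without 24 h replicate 1 and 36 h replicate 1 (0.0558), without 0 h replicates 1 (0.0596) or 3 (0.0563) and without 12 h replicates 1 (0.0681) or 2 (0.0816), and autophagy without 0 h replicate 2 (0.0637). At 72 h the size factors of DESeq2 ended the calls of CDK inhibitors (0.0544) and mitochondrial transcripts (0.0517). CDK inhibitors also lost theirs without 24 h replicate 1 and 36 h replicate 1 (0.0538), without 0 h replicates 1 (0.0514), 2 (0.0551) or 3 (0.0519) and without 72 h replicate 1 (0.0617). With SA heme synthesis lost its call without 12 h replicate 2 (0.0525) or SA replicate 3 (0.0834), membrane and skeleton without SA replicate 3 (0.122), and glucocorticoid targets without 12 h replicate 1 (0.102).

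Adding the replicate number as a block gave 84 genes with SA, all 47 among them, with 56 in the opposite and 20 in the same direction at 24 h. Other counts under the block stayed within 1.5 times, and list counts were 13, 18 and 11, with the respiratory chain list at 12 h not called (adjusted p = 0.0614). The numbers did not pair the libraries at 12 h and 0 h (r from 0.0618 to 0.465; 4 of 6 libraries correlated best with their own number), 36 h and 24 h (0.0281 to 0.317; 4 of 6), 24 h and 0 h (0.0344 to 0.292; 4 of 6) or 72 h and 0 h (-0.0566 to 0.0269; 1 of 6). There the block gave 6801, 9198, 8342 and 11172 genes.

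Of the 223 changes of named genes, 8 turned direction under at least 1 alternative and 19 lost and 7 gained a call under at least 1. With the compared libraries alone Alas2 (-0.304), Fech (-0.198), Hbb-bs (-0.634), Hbb-bt (-0.509) and Ddit3 (-0.345) were called with SA. Klf1 and Mki67 at 72 h against 0 h gained calls as described in the report. In TPM, with log2(TPM + 1), log2(TPM + 0.1) and the wider filter in turn, the values at 72 h against 0 h were -1.708, -1.711 and -1.708 for Rpl28, -2.629 in each for mt-Co1, -2.387, -2.422 and -2.387 for Nusap1, and -3.791, -3.861 and -3.791 for Mki67. For Alas2 at 72 h against 48 h they were -0.6969, -0.6973 and -0.6969, and for Eif2ak1 with SA 0.0001174, 0.0001183 and 0.0001174. The median of all genes in log2(TPM + 1) was -3.26 at 72 h against 0 h, so the scale as a whole lies lower there; for Alas2 and Eif2ak1 the cause was not tested. With no count filter Mki67 at 72 h was at -0.0838 and Alas2 at 72 h against 48 h at -0.0667. Klf1 at 72 h was at 0.0564 with the size factors of DESeq2 in edgeR and 0.0238 in DESeq2. Atf4 with SA was at -3.61e-05 with those size factors and -0.0103 with the compared libraries alone. In the reported test Klf1, Mki67, Alas2, Eif2ak1 and Atf4 were not called in these comparisons, and the cause of these turns was not tested. Without 1 library Atf4 was at -0.0232 to 0.0253, Mki67 at -0.1533 to 0.3658 and Alas2 at -0.1898 to 0.2166. In TPM with the wider filter Mx2 at 48 h against 36 h was at 0.388 and not called, against 3.17 and called in the reported test.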

Other observations

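Every test of the 3 patterns below was chosen after its result was seen, except the count of interferon genes; the splits of the libraries were planned, but not the exchange of times within replicate numbers. Markers of other blood cells went different ways. Summed megakaryocyte and platelet markers went from 19.9 ± 2.55 CPM at 0 h to 121 ± 6.33 CPM at 24 h, 1878 ± 123 CPM at 48 h and 1079 ± 262 CPM at 72 h (mean ± SD, n = 3). All 5 tested of 12 listed markers rose at 72 h against 0 h, with a median log2 change of 5.68 (1.72 in TPM), among them Itgb3 at 9.99 ± 0.58, Gp6 at 8.66 ± 0.18 and Itga2b at 5.68 ± 0.19 (SE). Summed mast cell markers went from 41.4 ± 6.27 CPM at 0 h to 6.80 ± 1.05 CPM at 24 h and 36.4 ± 4.14 CPM at 72 h. Of the 8 tested, 3 rose and 3 fell at 72 h, with Mcpt4 at 9.31 ± 0.31 and Hdc at -5.07 ± 0.28.

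Endothelial markers summed to 0.204 ± 0.0658 CPM at 0 h and 1.60 ± 0.328 CPM at 72 h, and pluripotency markers to 0.216 ± 0.0607 and 2.56 ± 1.21 CPM. Macrophage markers went from 0.835 ± 0.0313 to 11.5 ± 0.901 CPM, neutrophil markers from 0.0311 ± 0.0385 to 6.58 ± 1.19 CPM and lymphocyte markers from 0.141 ± 0.0582 to 4.71 ± 0.736 CPM. Of the 11 stromal markers none had enough counts to be tested. Among alpha globin counts, Hba-a1 took 65.4% in 48 h replicate 3 and 71.7% in 72 h replicate 3, and 24.1 to 34.4% in the other libraries of those times.

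Hypoxia-responsive genes were lower with SA, with a median log2 change of -0.90 over 30 genes. Scaling shifts all genes of a library alike, and this median lay -0.921 from that of all tested genes (2.31% of them lay below it). The list was put together after the SA values were seen, which favors low values with SA, so this gap is no test of scaling. A delay from 0 to 12 h would keep SA levels between those times, but 14 of the 30 genes had all 3 SA libraries below every library of 0 h and 12 h. The choice of the genes favors this count too, so it argues only weakly against a delay as the whole cause. A difference in culture conditions unrelated to SA may account for the pattern: in 24 h replicate 1, which had no SA, the median lay -1.004 from the other replicates. In 36 h replicate 1 it lay -0.814 from the others. Replicates 2 and 3 lay the other way, at 0.67 and 0.31 at 24 h and at 0.84 and 0.05 at 36 h. Each value is taken against the other replicates of its group, so a high replicate also lowers the rest. Within the compared groups the deviations were -0.19, 0.16 and 0.03 at 12 h and -0.01, 0.05 and -0.02 with SA. Such a difference would thus have had to set all 3 SA libraries apart from all 3 at 12 h, which the single libraries at 24 and 36 h do not show. An effect of SA stays open as well, since the labels give no culture conditions per library.

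Interferon-stimulated genes were higher from 36 h on. RNA of immune cells as the source is argued against by a marker sum of 22.8 CPM at 72 h, 0.114% of the 20029.9 CPM of these genes, and scaling by a median log2 change of 3.43 at 72 h against 0 h in TPM, where the median of all genes was -3.27. Interferon made by the cells themselves cannot be told apart from other sources by counts this low: the 20 interferon genes had together 18, 15 and 27 counts in the 72 h libraries, 7, 7 and 4 at 48 h and 1, 3 and 4 at 36 h, so the lowest was 1, while 12 h replicate 2 had 10 and each 24 h library 0. Ifnb1 and Ifna4 went with the stimulated genes, at 0 counts in the groups of 0, 12 and 24 h, with SA too, and at 3, 11 and 32 and at 2, 4 and 9 at 36, 48 and 72 h, and of the counts at 12 h without SA 8 were of Ifnz. A response to nucleic acids in maturing cells, which differentiation could bring, was not tested.

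Stromal transcripts stood out in 36 h replicate 1, at 33.3 CPM over 11 markers, led by Col3a1 (12.3 CPM), Sparc (5.06 CPM) and Col1a1 (4.60 CPM). RNA from stromal cells in that library is a candidate source, since 9 of the 11 markers had 10 or more counts there. Carry-over from another library of the series is argued against, as the highest of the other 20 libraries reached 1.96 CPM. The labels name no sort of the cells, and no biological explanation was tested.

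With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, so the values stand alone. In 1 of 10 splits, the real one, the counts of genes were as large as reported: 6539 at 12 h against 0 h (highest other 0), 5079 at 24 h against 12 h (0), 9044 at 36 h against 24 h (4), 6153 at 48 h against 36 h (1), 7322 at 72 h against 48 h (20), 11102 at 72 h against 0 h (0), 8151 at 24 h against 0 h (0) and 47 with SA (2). For SA genes with the opposite direction at 24 h it was also 1 of 10 (33, highest other 2). The other splits mix both groups on each side, which widens the spread and lowers their calls. Their low counts of genes therefore do not exclude chance. Counts of lists were as large in 4 of 10 splits at 12 h against 0 h (14, others 10 to 16), 1 of 10 at 72 h against 0 h (18, others 10 to 17) and 2 of 10 with SA (9, others 3 to 9). Splits with 0 genes called thus still called lists. Part of the real change stays in each of them, since its sides hold unequal numbers of both groups. They therefore cannot show whether the p-values of camera with the preset correlation are too small. Fewer lists were called with an estimated correlation, so those p-values cannot be taken at face value. Where replicate numbers pair the libraries, the splits that part every pair reached at most 0 genes at 24 h against 12 h, 48 h against 36 h and 72 h against 48 h, and 2 genes and 9 lists with SA; the other splits keep at least 1 pair of same-numbered libraries on the same side. Of 100 groupings of the 18 libraries without SA, the real one included, 1 gave as many time course genes as the real 12059 (highest other 5953). As many transient genes as the real 1936 came from 3 of them (highest other 3711). Both shares are under 0.05. Random groupings mix times within a group, however, which widens the spread and lowers their calls, so chance is not excluded. With the times exchanged only within each replicate number, chosen after the first groupings were seen, these were 1 of 100 (highest other 9487) and 4 of 100 (highest other 6654). These shares are also under 0.05, with the same limit. The groupings with more transient genes than the real one gave 3711 and 2741 in the first set and 6654, 3471 and 2842 in the second. Why these groupings gave more transient genes than the real one was not tested.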
